A study of Mus musculus with 7 samples.

How the data were processed

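Total RNA of sorted splenic germinal centre B cells from immunized mice was biotin-labelled and hybridised to 1 whole-transcript Affymetrix array per sample, per the labels' protocols. The authors' deposited values are log2 intensities per transcript cluster. The submitters' processing notes name RMA, which corrects background, normalizes quantiles and summarises probes by median polish, and the package oligo, both without a version. The values ran from about 2 to 13 on each array, their medians lay between 4.34 and 4.54, and the genes were not centred. RMA gives all arrays of a run nearly the same distribution of values at the level of single probes, whereas the interquartile range of the deposited values ran from 2.37 to 2.91. How that spread arose is not given in the sources used here. Scanner files were not used here. The number of arrays, not a read depth, limits the precision.

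Samples were grouped by the genotype in their labels, 4 WT and 3 RRas2-deficient. The labels call them biological replicates without naming the animals, and p-values measure the spread between these samples. No 2 arrays held identical values, and the highest correlation between a pair was 0.993. In the tested genes 7786 (48.3%) had the same value on at least 2 arrays to 8 digits, as median polish of few probes can give.

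Genes were named from the platform annotation of the array, in which 22225 probes had 1 gene symbol, 616 several and 2508 none, and no gene was named from the last 2 kinds. For 22107 of the probes with 1 symbol the gene ID was found in a RefSeq table of mouse genes, and 0 symbols changed. That table was also used to place genes by chromosome and order, and none of its coordinates is given because the build behind the annotation is not given in the sources used here. Of several probes of a gene (640 of 21515 genes) the brightest in the mean over all arrays was kept. Genes with a mean under the 25th percentile of all genes (3.48 on the log2 scale) were left out, which kept 16136 and removed 5379.

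Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, RRas2-deficient minus WT, two-sided, no covariate), with Benjamini-Hochberg adjustment over the 16136 genes and a threshold of 0.05. Every unadjusted or adjusted p of a gene is limma's, and the error given beside a log2 difference is limma's moderated standard error. For Rras2 an exact permutation test over the 35 splits of 7 arrays into 4 and 3 was added. Before the data were examined, 43 gene lists were fixed, of which 41 had at least 5 tested members and were tested as groups. They covered energy, lipid and growth metabolism, signalling, germinal centre and other B cell states, proliferation, stress responses and markers of other spleen cells. The lists of mitochondrial DNA genes (0 of 13 measured) and of sex-linked genes (a sample check) were not tested. Lists were tested with camera at its preset correlation of 0.01, adjusted over the 41 lists, and again with the correlation estimated for each list. The value after a list's mean in the text is its adjusted p from camera, higher and lower count members by the sign of their difference, and a list's mean intensity is the mean over its members on an array.

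The genes named in the text follow a rule fixed before the data were examined. It takes Rras2; the 12 genes of each direction that passed without overlap of the genotypes, by size, filled up by lowest unadjusted p; up to 4 members of lowest p of each list that passed and of each energy and germinal centre list; bright markers of other cells; and the RAS subfamily. Predicted genes and families such as olfactory receptors were only counted there, which left out 1 gene that passed, Gm1966.

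Alternatives fixed before the data were examined were other filters on dim genes, the mean over probes, a further quantile normalization, centring on medians, an intensity trend with a robust prior, array weights (statmod 1.5.0), the replicate number as a block (which also sets WT replicate 4 aside, since it has no partner), a plain t-test, a fold limit of 1.5, all probes, leaving out each array, and other list tests (fry and exact permutation). Chosen after seeing the data were the array set as a block, parted at the widest gap in interquartile range (0.197, at 2.59), the interquartile range as a covariate, each set alone, leaving out each array with the block, and lists without genes of the chromosome of Rras2.

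The tests were run on simulated data for the comparison of RRas2-deficient with WT over 16136 genes. With noise taken from the residuals of the genotype fit, 4.48% of genes changed 1.5-fold, 29.9% of those changed 2-fold and 86.4% of those changed 4-fold were recovered. Such noise leaves an unchanged gene with a difference of 0, so the 0 false calls among 80 were fixed in advance. It also leaves the estimate of a changed gene equal to the change set, with a slope of 1 at each fold. These shares therefore hold no error of the estimate and do not give the share that new arrays would recover. With independent noise the shares were 16.4%, 47.8% and 87.9%, with 4 false calls among 105. With the residual noise and the array set as a block they were 29.9%, 77.6% and 98.5%. There were 0 false calls among 137 there. That noise held no difference between the genotype means, but the sets are unevenly shared between the genotypes, so the block can bring one in. The slope of estimate on change was 0.981 at 1.5-fold, 1.00 at 2-fold and 0.985 at 4-fold. These 0 false calls were thus not strictly fixed, but they come from noise made without a genotype difference. A list shifted by 0.30 on independent noise was called by camera, and 0 other lists were. Genes of a list are not correlated in such noise, whereas the estimated correlation was 0.46 for the MYC list. That run therefore cannot show how often camera calls unshifted lists in the real data. Figures were drawn with matplotlib 3.10.9.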

Results

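Germinal centres are the sites in spleen and lymph node where B cells activated with T cell help divide, mutate their antibody genes and switch isotype. The series asked how messenger RNA differs in germinal centre B cells of mice that lack R-Ras2, a small GTPase of the RAS superfamily encoded by Rras2. Its title links the protein to the energy demand of these cells. Splenic B cells with the surface markers B220, CD95 and GL7 were sorted by flow cytometry 7 days after an injection of sheep red blood cells, a standard T cell-dependent immunogen. Total RNA was read on a whole-transcript Affymetrix array, with 4 arrays from wild-type (WT) mice and 3 from RRas2-deficient mice, which the labels call biological replicates. Each array gave 25349 log2 intensities, and 16136 genes were bright enough to be tested. An array has no read depth, and the number of arrays limits the precision.

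The 7 arrays fell into 2 sets that cut across genotype. The interquartile range of the log2 intensities was 2.37 in WT replicate 1, 2.49 in WT replicate 2 and 2.40 in RRas2-deficient replicate 2. It was 2.91 in WT replicate 3, 2.78 in WT replicate 4, 2.73 in RRas2-deficient replicate 1 and 2.69 in RRas2-deficient replicate 3. The first principal component held 73.0% of the variance and parted the same 3 arrays from the other 4. Pearson correlations across probes were 0.981 to 0.993 for the 9 pairs of arrays within a set and 0.948 to 0.976 for the 12 pairs between sets. The mean log2 intensity of the oxidative phosphorylation list was 6.52, 6.63 and 6.48 on the 3 narrower arrays and 7.34 to 7.69 on the 4 wider ones. The list of immediate early genes, such as Fos and Egr1, which cells switch on within minutes of a stimulus or of tissue dissociation, ran the other way, at 7.42 to 7.80 on the narrower arrays and 6.33 to 6.94 on the wider ones. Both genotypes occur in each set. The genotype difference from a limma model that holds the set as a block therefore stands beside each result whose call it changes. That block was chosen after seeing the data, and it does not remove all of the spread. Within the wider set both WT arrays had a larger interquartile range than both deficient arrays, so spread and genotype stay partly mixed there.

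**Figure D1:**
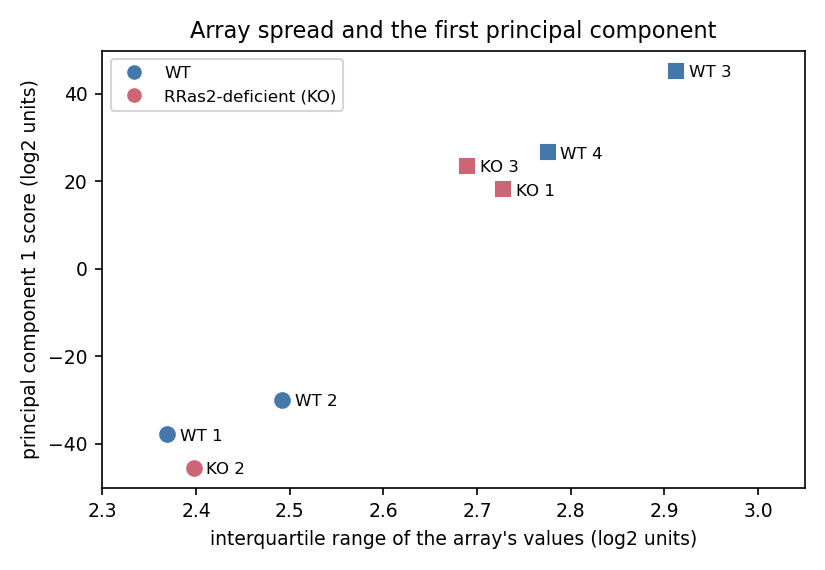
Score on the first principal component (log2 units) against the interquartile range of the log2 intensities, 1 point per array, with WT and RRas2-deficient (KO) arrays in separate colours and the narrower and wider sets as circles and squares. WT replicates 1 and 2 and RRas2-deficient replicate 2 lie between 2.37 and 2.49, and the other 4 arrays between 2.69 and 2.91.

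Rras2 itself was lower in the deficient cells in the mean, and its change did not pass the test over all genes. Its single probe (gene ID 66922) read 7.13, 7.41, 8.66 and 8.39 in WT replicates 1 to 4 and 6.93, 6.68 and 7.12 in RRas2-deficient replicates 1 to 3. The group means were 7.90 ± 0.74 (SD, n = 4) and 6.91 ± 0.22 (SD, n = 3) on the log2 scale, a difference of -0.99 ± 0.39 (SE) and a 1.98-fold lower level. The highest deficient array lay just under the lowest WT array. The unadjusted limma p was 0.0415 and the adjusted p was 1.00, and a two-sided exact permutation test over the 35 splits gave p = 0.114, where the smallest p it can give is 0.0286. The difference was -0.59 within the 3 narrower arrays and -1.50 within the 4 wider ones. The blocked model gave -1.13 ± 0.20 (SE), with an unadjusted p of 0.000769 and an adjusted p of 0.296. The labels do not say which part of the gene is missing, and a probe outside that part would check nothing.

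In RRas2-deficient germinal centre B cells 2 genes fell past an adjusted p of 0.05 and 0 rose. Trim12a (gene ID 76681), of the tripartite motif family of antiviral and ubiquitin ligase proteins, fell from 7.79 ± 0.30 (SD, n = 4) to 5.20 ± 0.24 (SD, n = 3), a log2 change of -2.59 ± 0.19 (SE) or 6.01-fold, with a limma adjusted p of 0.0310. The predicted gene Gm1966 (gene ID 434223) fell from 7.32 ± 0.25 (SD, n = 4) to 3.63 ± 0.31 (SD, n = 3), a log2 change of -3.69 ± 0.19 (SE), with a limma adjusted p of 0.00567. The deficient arrays read 3.29 to 3.88, near the limit of 3.48 for dim genes, so the size of its change is uncertain. Its kind of name was outside the rule for named genes, so it was named after its value was seen. Both passed with the array set as a block as well, where Gm1966 differed by -3.65 and Trim12a by -2.62. Gm1966 lost its call without WT replicate 1 (adjusted p = 0.0820), WT replicate 4 (0.0730), RRas2-deficient replicate 2 (0.102) or RRas2-deficient replicate 3 (0.0520), with log2 changes between -3.81 and -3.69 in these 4 fits. With the block it lost its call without RRas2-deficient replicate 2 (0.0971) and kept it without any other 1 array (adjusted p = 0.00212 to 0.0455). Trim12a lost its call without any 1 of the 7 arrays, with log2 changes between -2.70 and -2.45, and with the block it kept it without RRas2-deficient replicate 1 (adjusted p = 0.0258) and in none of the other 6 fits.

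**Figure D2:**
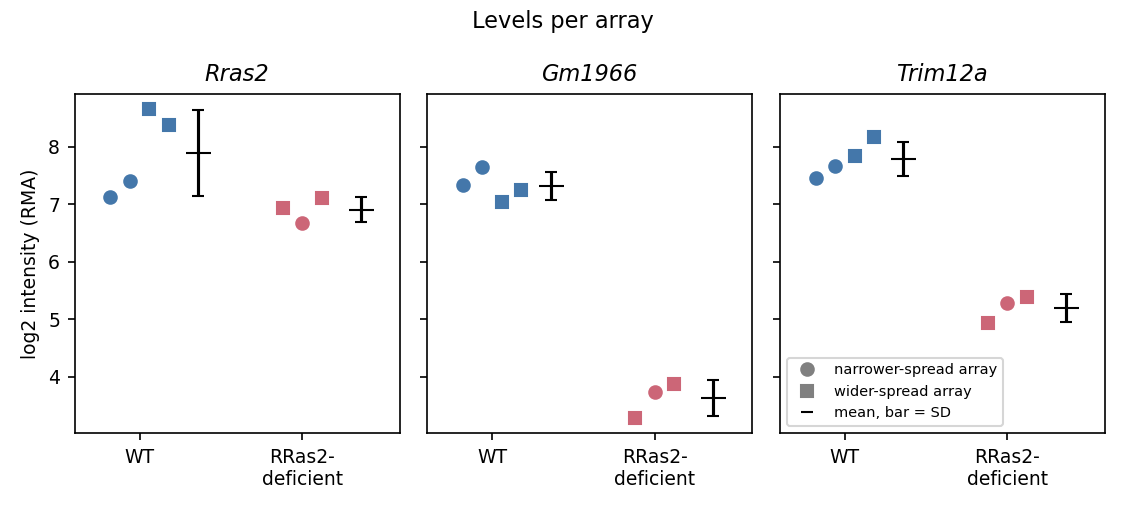
Log2 intensity of Rras2, Gm1966 and Trim12a on each of the 7 arrays, with the mean and SD of each genotype beside the points; circles are arrays of the narrower set and squares arrays of the wider set. Gm1966 read 7.05 to 7.65 on the WT arrays and 3.29 to 3.88 on the RRas2-deficient arrays.

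The other genes named by the rule did not pass the test, and their values are given for description. Among those with higher means in the deficient cells were Il9r, the interleukin-9 receptor (1.45 ± 0.23, log2 difference ± SE), Inppl1, the phosphoinositide phosphatase SHIP2 (0.56 ± 0.10), Trim12c (1.71 ± 0.32), Cacna1e, a voltage-gated calcium channel subunit (0.74 ± 0.16), Gdpd3 (1.61 ± 0.35) and the orphan receptor Gprc5b (1.00 ± 0.23). Map3k21 (0.45), Carmil1 (0.68), Vsig10 (0.29), Smim6 (0.59), the transcriptional repressor Bach1 (0.29) and the transcription factor gene Scx (0.55) completed the 12. Among those with lower means were Trim30b (-0.79 ± 0.11), Fcrl5, an Fc receptor-like protein of marginal zone and B-1 B cells (-0.57 ± 0.11), Trim34a (-1.79 ± 0.34), Nucb2 (-0.84 ± 0.17), Shisa8 (-0.58 ± 0.15) and Alg8, a glucosyltransferase of N-glycan assembly (-1.20 ± 0.32). Wdr11 (-0.59), Sh2d2a, a lymphocyte signalling adapter (-0.36), the RNA gene Snhg15 (-0.39), Sla, an adapter that dampens antigen receptor signalling (-0.42), and Trim30d (-1.03) followed. Some mean log2 intensities lay near the limit of 3.48 for dim genes, so the sizes of those differences are uncertain. These were Trim12c (3.20), Map3k21 (3.56) and Vsig10 (3.56) in WT cells and Trim30b (3.51) and Trim30d (3.73) in deficient cells. Trim30b had an adjusted p of 0.747, and the adjusted p of the others was 1.00. At an unadjusted p under 0.05 there were 132 genes, 84 higher and 48 lower, against 807 expected by chance. With the array set as a block there were 1634, 627 higher and 1007 lower, and the same 2 genes passed the adjusted threshold. In 175 genes (1.08%) the genotypes did not overlap, where chance gives 5.71%.

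Of the 20 genes with the lowest unadjusted p, 11 lie on the chromosome of Rras2, where 1.67 would be expected from the 1346 of 16068 tested genes placed there (one-sided Fisher's exact test, p = 1.12e-07). These 11 are Nucb2, Gprc5b, Gm1966, Gm4759, Trim30b, Trim12c, Trim12a, Trim34a, Gdpd3, Inppl1 and Alg8, of which 4 had higher and 7 lower means in the deficient cells. They sat 11 to 191 genes from Rras2 in gene order. Their median distance was 81 genes, against 337 for the other tested genes of that chromosome, a comparison made after the values were seen (permutation p = 0.00079). The Trim genes among them sat 80 to 83 genes from Rras2, and Gm1966 and Gm4759 sat 52 and 54 away. Both tests take genes as independent, which such clustered genes need not be, so both p-values are likely too small.

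**Figure D3:**
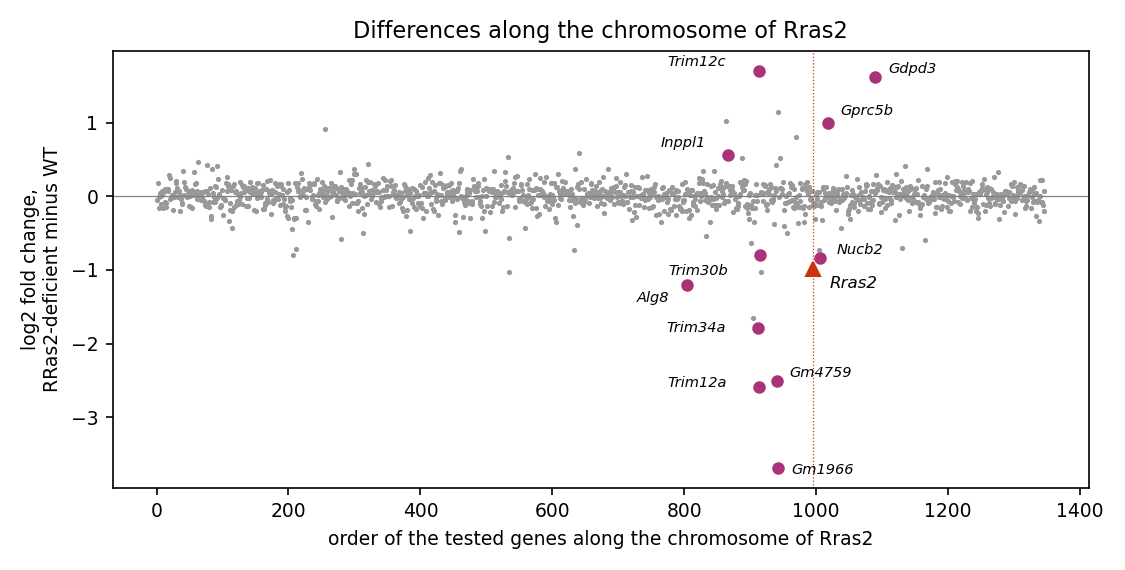
Log2 difference between RRas2-deficient and WT cells of each tested gene on the chromosome of Rras2, against its place in the order of the tested genes, with Rras2 as a triangle and dotted line and the 11 genes among the 20 of lowest p marked and named. The marked genes sit 11 to 191 genes from Rras2, and Gm1966 (-3.69) and Trim12a (-2.59) are the lowest of them.

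The growth programme driven by the transcription factor MYC had lower means in the deficient cells for most of its genes. Of 47 MYC target and ribosome biogenesis genes tested, 42 were lower and 5 higher, with a mean log2 difference of -0.14, and camera called the list against all other genes (adjusted p = 0.00746). The call was lost with the correlation between genes estimated from the data (adjusted p = 0.985 with an estimated correlation). No member passed singly. The members of lowest p included Ccnd2, a D-type cyclin (-0.58 ± 0.23), and 3 with higher means, the ribosome assembly factors Rrs1 (0.45 ± 0.16) and Rrp9 (0.16 ± 0.11) and the MYC antagonist Mxi1 (0.25 ± 0.12). With the array set as a block the mean was -0.24, with 40 of 47 genes lower and a camera adjusted p of 1.50e-07 (adjusted p = 0.707 with an estimated correlation). It was -0.10 with the interquartile range as a covariate in place of the sets (camera adjusted p = 0.00234, and adjusted p = 0.627 with an estimated correlation). The list's mean intensity itself followed the array sets, at 6.94 to 7.18 on the narrower arrays and 7.42 to 7.87 on the wider ones. Without the block the mean was 0.00 without WT replicate 3, -0.10 without WT replicate 4 and 0.03 without RRas2-deficient replicate 2, and the list passed in none of these 3 fits. WT replicate 3 also stood apart from the other 6 arrays in its sex-linked genes. The list also did not pass with the arrays centred on their medians (-0.16, adjusted p = 0.0757).

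Genes of amino acid uptake and of the ATF4 response to amino acid shortage were lower in 25 of 33 cases, with a mean of -0.11 and a camera adjusted p of 0.00746 (adjusted p = 0.985 with an estimated correlation). The stress-induced mTOR inhibitor Ddit4 differed by -0.30 ± 0.13, the amino acid transporters Slc38a2 and Slc1a5 by -0.19 ± 0.12 and -0.13 ± 0.11, and Nupr1 by -0.12 ± 0.10. Genes of the unfolded protein and heat shock response were lower in 18 of 25 cases, with a mean of -0.17 and an adjusted p of 0.0296 (adjusted p = 0.985 with an estimated correlation). The endoplasmic reticulum co-chaperones Dnajb9 and Sdf2l1 differed by -0.52 ± 0.25 and -0.28 ± 0.18, the stress sensor gene Ern1 by -0.12 ± 0.08 and the inducible heat shock protein gene Hspa1a by -0.97 ± 1.00. That of Hspa1a rested on WT replicate 1, which read 7.89 against 3.68 to 4.48 on the other WT arrays. In the blocked model the means were -0.18 for the ATF4 list (camera adjusted p = 0.000165) and -0.20 for the unfolded protein list (0.00227), and both were lost with an estimated correlation (adjusted p = 0.707 with an estimated correlation for each). The covariate in place of the block gave -0.07 for the ATF4 list (camera adjusted p = 0.0451, and adjusted p = 0.627 with an estimated correlation) and -0.15 for the unfolded protein list, which did not pass (0.0648). Neither list passed with a further quantile normalization (adjusted p = 0.0740 for each), with the replicate number as a block (0.125 and 0.164) or on the 3 narrower arrays (0.807 and 0.180), of which 1 is from deficient cells, and the unfolded protein list also not with the arrays centred (0.0757). The ATF4 list did not pass without WT replicate 3 (0.01), WT replicate 4 (-0.05) or RRas2-deficient replicate 2 (0.00). The unfolded protein list did not pass without WT replicate 3 (-0.13), WT replicate 4 (-0.14), RRas2-deficient replicate 1 (-0.14) or RRas2-deficient replicate 2 (-0.09). With the array set as a block the unfolded protein list lost its call without RRas2-deficient replicate 1 (camera adjusted p = 0.0902). It kept that call without any other 1 array.

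All 25 tested genes of the type I interferon response had higher means in the deficient cells, with a mean log2 difference of 0.26 and a camera adjusted p of 2.08e-07 (adjusted p = 0.985 with an estimated correlation). The 2'-5' oligoadenylate synthetase genes Oas2 and Oas3, which act against viral RNA, differed by 0.45 ± 0.17 and 0.44 ± 0.21, the RNA sensor gene Dhx58 by 0.41 ± 0.20 and the related Oasl1 by 0.34 ± 0.20, and none passed singly. The difference rested on RRas2-deficient replicate 3: the list's mean intensity was 6.44 there and 5.57 to 5.78 on the other 6 arrays. The mean intensity of the monocyte, macrophage and dendritic cell markers was also highest there, at 5.28 against 4.84 to 5.09 on the others. Without that array the mean difference was 0.01 and the list did not pass (adjusted p = 0.813). In the blocked model it was 0.21 (camera adjusted p = 0.000183, and adjusted p = 0.707 with an estimated correlation), and with the covariate 0.28 (camera adjusted p = 6.31e-06, and adjusted p = 0.627 with an estimated correlation).

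The 6 tested lists of energy metabolism did not pass in the comparison of genotypes. Of 68 nuclear genes of oxidative phosphorylation 31 were higher and 37 lower (mean -0.01, camera adjusted p = 0.779), with the complex I subunit genes Ndufb10 (0.29 ± 0.23) and Ndufb7 (0.12 ± 0.10) and the ATP synthase genes Atp5k (0.24 ± 0.14) and Atp5c1 (-0.23 ± 0.20) of lowest p. In the tricarboxylic acid cycle 20 of 30 genes were lower (mean -0.08, 0.198); the isocitrate dehydrogenase subunit gene Idh3a differed by -0.69 ± 0.63, Dlst by -0.17 ± 0.12, and the pyruvate dehydrogenase kinase genes Pdk1 and Pdk4 by -0.16 ± 0.12 and 0.18 ± 0.16. In glycolysis 15 of 19 genes were lower (mean -0.09, 0.103), among them the glucose transporter gene Slc2a3 (-0.19 ± 0.09) and the phosphofructokinase gene Pfkp (-0.31 ± 0.27), while Hk3 (0.10 ± 0.09) and Ldhb (0.13 ± 0.12) were higher. In fatty acid oxidation 19 of 24 genes were lower (mean -0.08, 0.194), among them the carnitine shuttle genes Cpt2 (-0.21 ± 0.14) and Slc25a20 (-0.24 ± 0.20), with Decr1 (0.19 ± 0.12) and Hadhb (0.21 ± 0.17) higher. Genes that maintain mitochondrial DNA and translate its messages were 29 higher and 29 lower (mean 0.00, 0.994), with the mitochondrial ribosomal protein genes Mrpl12 (0.49 ± 0.17), Mrps2 (0.38 ± 0.20) and Mrpl24 (-0.34 ± 0.18) and the termination factor family gene Mterf4 (0.22 ± 0.11) of lowest p. Genes of mitochondrial import, biogenesis and dynamics were lower in 24 of 36 cases (mean -0.06, 0.414), with Timm10 at -0.19 ± 0.22, Timm13 at 0.09 ± 0.11, the fusion gene Mfn2 at 0.18 ± 0.21 and the chaperonin gene Hspd1 at -0.40 ± 0.53. The 13 protein genes of mitochondrial DNA itself were not analysed here.

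With the array set as a block, all 6 of these energy lists passed camera with lower means in the deficient cells. Oxidative phosphorylation had 52 of 68 genes lower (mean -0.17, adjusted p = 2.05e-06), the tricarboxylic acid cycle 27 of 30 (-0.23, 7.63e-06), glycolysis 15 of 19 (-0.14, 0.0300), fatty acid oxidation 20 of 24 (-0.19, 0.000151), mitochondrial DNA maintenance and translation 39 of 58 (-0.09, 0.0262) and mitochondrial import 27 of 36 (-0.17, 0.000165). All 6 were lost with an estimated correlation (adjusted p = 0.707 with an estimated correlation for each), and no member passed singly. Idh3a was the named member with the largest blocked difference, at -0.96 (adjusted p = 0.275). With the interquartile range as a numeric covariate in place of the 2 sets none of the 6 passed. The means were 0.07 for oxidative phosphorylation (camera adjusted p = 0.142), -0.01 for the tricarboxylic acid cycle (0.423), -0.06 for glycolysis (0.126), -0.03 for fatty acid oxidation (0.313), 0.05 for mitochondrial DNA maintenance (0.310) and 0.00 for mitochondrial import (0.986). Without the block, leaving out 1 array moved the mean of oxidative phosphorylation between -0.19 (without WT replicate 1) and 0.29 (without RRas2-deficient replicate 2). The list passed in 5 of these 7 fits, in 3 as lower and in 2 as higher in the deficient cells, with adjusted p = 0.0139 and 0.000300 at the 2 ends. The tricarboxylic acid cycle moved between -0.26 (without WT replicate 1, adjusted p = 0.00275) and 0.19 (without RRas2-deficient replicate 2, 0.142), and passed as lower in 4 of the 7. With the block, oxidative phosphorylation was lower and passed in all 7 such fits (-0.22 to -0.11, adjusted p from 6.96e-07 to 0.000388), and so was the tricarboxylic acid cycle (-0.30 to -0.14, 6.96e-07 to 0.000388). Glycolysis and mitochondrial DNA maintenance lost their blocked calls without WT replicate 2 (-0.13 and -0.07), WT replicate 3 (-0.07 and -0.03) or RRas2-deficient replicate 3 (-0.12 and -0.08).

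**Figure D4:**
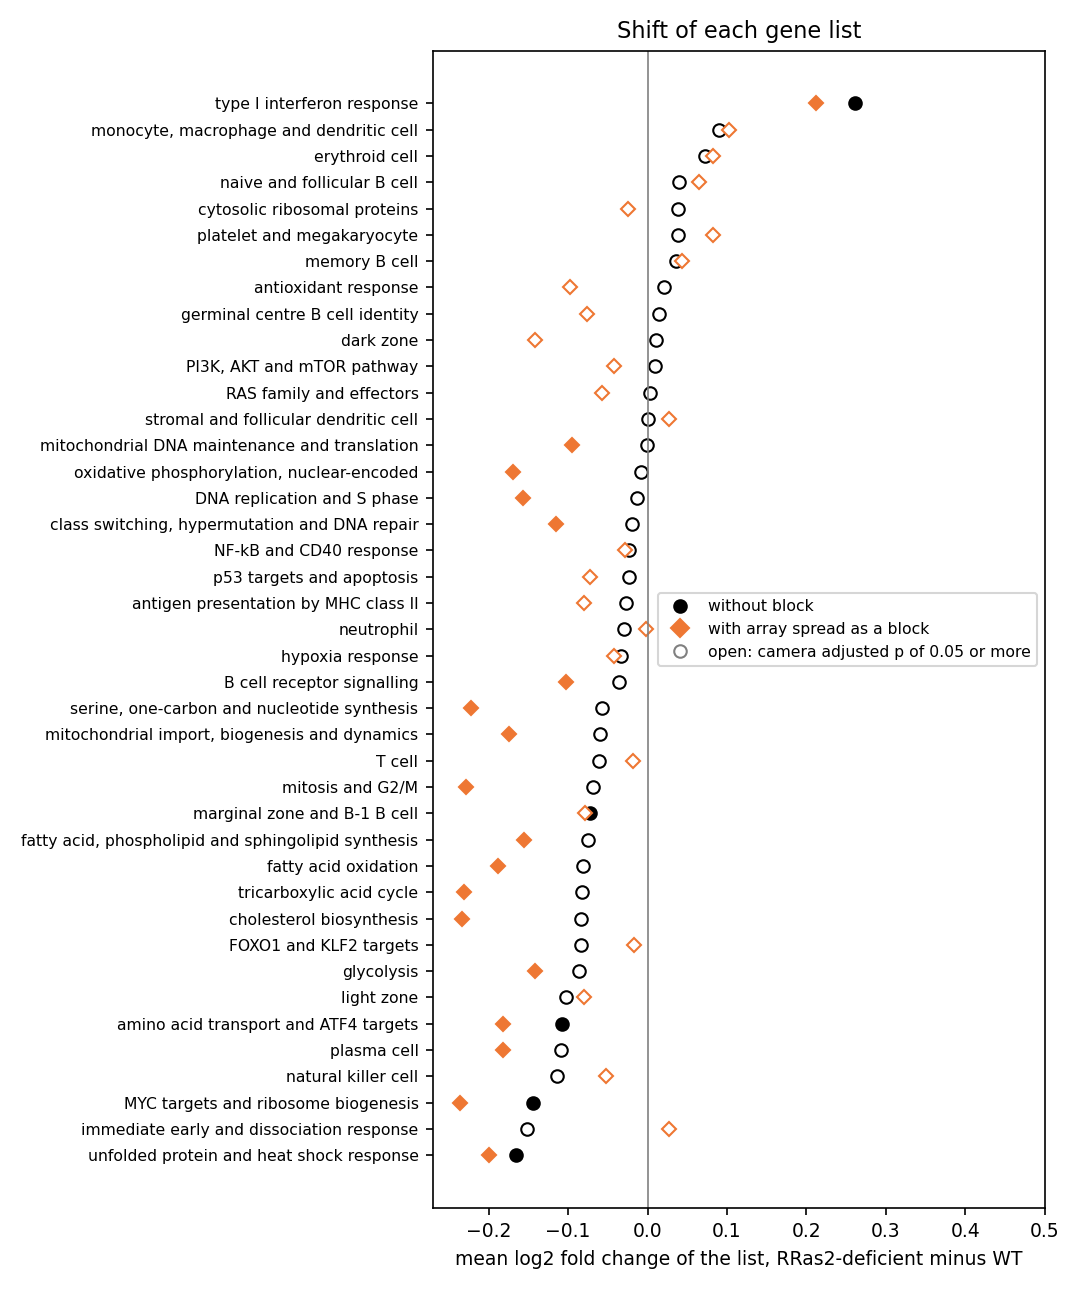
Mean log2 difference between RRas2-deficient and WT cells over the genes of each list, from the comparison of genotypes alone (circles) and with the array set as a block (diamonds), filled where the camera adjusted p was under 0.05. The type I interferon list stands at 0.26 and 0.21, the MYC list at -0.14 and -0.24, and oxidative phosphorylation at -0.01 and -0.17.

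The 3 biosynthetic lists did not pass either. Cholesterol synthesis had 13 of 19 genes lower (mean -0.08, camera adjusted p = 0.270), synthesis of fatty acids, phospholipids and sphingolipids 19 of 28 (-0.07, 0.199), and synthesis of serine, one-carbon units and nucleotides 19 of 26 (-0.06, 0.468). They passed once the array set was a block, with means of -0.23, -0.16 and -0.22 (adjusted p = 0.000165, 0.00557 and 0.000141), and were lost with an estimated correlation (adjusted p = 0.707 with an estimated correlation for each). The covariate in place of the block gave -0.01, -0.03 and 0.03, and none passed (adjusted p = 0.572, 0.423 and 0.994). The cytosolic ribosomal protein genes did not pass, with 19 of 32 higher (mean 0.04, 0.655).

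Lists of germinal centre identity and its zones did not pass between genotypes. Of 32 germinal centre B cell identity genes 18 were higher and 14 lower (mean 0.01, camera adjusted p = 0.779), with the B lineage factor gene Pax5 at 0.15 ± 0.10, Ephb4 at 0.14 ± 0.12, Gpr174 at 0.09 ± 0.10 and Clec2i at -0.16 ± 0.15. Of 17 genes of the dark zone, where germinal centre B cells divide and mutate, 8 were higher and 9 lower (mean 0.01, 0.918), with the ligase gene Lig1 at 0.26 ± 0.27, Neil1 at 0.24 ± 0.31, Tcf3 at 0.16 ± 0.20 and Hmmr at -0.25 ± 0.43. Of 26 genes of the light zone, where they are selected by T cell help, 16 were lower (mean -0.10, 0.101), among them Ccnd2, Icam1 (-0.21 ± 0.14), Egr2 (-0.20 ± 0.15) and Gadd45b (-0.15 ± 0.11). Of 27 plasma cell genes 21 were lower (mean -0.11, 0.0953), among them the plasma cell regulators Prdm1 (-0.27 ± 0.19) and Irf4 (-0.48 ± 0.43), Derl3 (-0.40 ± 0.26) and the BCMA gene Tnfrsf17 (-0.16 ± 0.15). In the blocked model the identity mean was -0.08 (0.228) and the dark zone mean -0.14 (0.143), and neither passed. The plasma cell list passed with the array set as a block, with 23 of 27 lower and a mean of -0.18 (camera adjusted p = 0.00162, and adjusted p = 0.707 with an estimated correlation), and not with the covariate (-0.07, 0.366).

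Marginal zone and B-1 B cell genes were lower in 13 of 18 cases, with a mean of -0.07 and a camera adjusted p of 0.0329 (adjusted p = 0.985 with an estimated correlation). Fcrl5 was the 1 member that passed when adjusted over the list alone, and 0 passed over all genes tested. Cd1d1 differed by -0.12 ± 0.08, Cd9 by -0.15 ± 0.13 and Lpcat2 by 0.29 ± 0.20. The list did not pass with the array set as a block (mean -0.08, adjusted p = 0.219) or with the covariate (-0.07, 0.100). Its call was also lost without the filter on dim genes (adjusted p = 0.0521), with the mean over probes (0.0702), with a further quantile normalization (0.0740), with the arrays centred (0.0757), with array weights (0.0542), with the replicate number as a block (0.164), on the 4 wider arrays or the 3 narrower ones, with 1 deficient array, alone (0.638 and 0.294) or without genes of the chromosome of Rras2 (0.0626). It also did not pass without WT replicate 2 (-0.05), WT replicate 4 (-0.05), RRas2-deficient replicate 1 (-0.06) or RRas2-deficient replicate 2 (-0.05). Naive and follicular B cell genes were 10 higher and 11 lower (mean 0.04, 0.779), with Ltb at 0.46 ± 0.18, the CD23 gene Fcer2a at 0.42 ± 0.18, the IgM Fc receptor gene Fcmr at -0.32 ± 0.11 and Zbtb20 at -0.16 ± 0.13. Memory B cell genes were 8 higher and 9 lower (mean 0.04, 0.779), with Pdcd1lg2 at 0.35 ± 0.17, Ccr6 at -0.13 ± 0.12 and Zbtb32 at -0.09 ± 0.09.

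Genes of class switching, hypermutation and DNA repair were 15 higher and 18 lower (mean -0.02, camera adjusted p = 0.520), with the uracil glycosylase gene Ung at -0.23 ± 0.24, the end-joining genes Xrcc5 and Nhej1 at -0.39 ± 0.41 and -0.12 ± 0.10, and Rnf8 at -0.13 ± 0.10. Antigen presentation genes of MHC class II were 9 higher and 9 lower (mean -0.03, 0.662), with the class II transactivator gene Ciita at 0.15 ± 0.09, H2-Ob at -0.27 ± 0.18, H2-DMb2 at -0.11 ± 0.10 and Rfxap at 0.19 ± 0.19. Proliferation genes gave 23 of 45 lower for DNA replication and S phase (mean -0.01, 0.701) and 33 of 42 lower for mitosis (mean -0.07, 0.270). In the blocked model class switching (26 of 33 lower, mean -0.12, adjusted p = 0.0106), S phase (37 of 45, -0.16, 0.000151) and mitosis (40 of 42, -0.23, 2.83e-05) passed. Each was lost with an estimated correlation (adjusted p = 0.707 with an estimated correlation). With the covariate in place of the block the means were 0.03, 0.06 and 0.01, and none passed (adjusted p = 0.711, 0.138 and 0.986). The list means of S phase were 7.22 to 7.49 on the narrower arrays and 8.05 to 8.47 on the wider ones. Genes of p53 and apoptosis did not pass, with 16 of 28 lower (mean -0.02, 0.520).

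RAS and antigen receptor signalling genes did not pass as groups. Of the close relatives of Rras2, Nras differed by 0.07 ± 0.14, Rras by 0.07 ± 0.19 and Mras by -0.04 ± 0.15. The RAS family and effector list, which holds Rras2, was 19 higher and 18 lower (mean 0.00, camera adjusted p = 0.779). The PI3K, AKT and mTOR list was 20 higher and 20 lower (mean 0.01, 0.798), and Inppl1 was the 1 member that passed when adjusted over the list alone, with 0 over all genes tested. FOXO1 and KLF2 targets were lower in 13 of 15 cases (mean -0.08, 0.231) and NF-kB and CD40 response genes in 13 of 22 (mean -0.02, 0.701). B cell receptor signalling genes were lower in 17 of 28 cases (mean -0.04, 0.520) and passed with the array set as a block (mean -0.10, adjusted p = 0.0283, and adjusted p = 0.707 with an estimated correlation), and not with the covariate (0.00, 0.921). Immediate early genes were lower in 19 of 26 cases (mean -0.15, 0.0661), with a mean of 0.03 once the array set was a block (0.580) and of -0.24 with the interquartile range as a covariate (0.000261, and adjusted p = 0.627 with an estimated correlation). Hypoxia response genes (15 of 23 lower, mean -0.03, 0.164) and antioxidant genes (12 of 21 higher, mean 0.02, 0.779) did not pass either.

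Markers of other spleen cells did not pass in any list. T cell markers had a mean of -0.06 (10 of 16 lower, camera adjusted p = 0.398), natural killer cell markers -0.11 (3 of 5 lower, 0.389), monocyte, macrophage and dendritic cell markers 0.09 (20 of 26 higher, 0.164) and neutrophil markers -0.03 (5 of 9 lower, 0.546). Erythroid markers had a mean of 0.07 (8 of 12 higher, 0.520), platelet markers 0.04 (5 of 7 higher, 0.779) and stromal and follicular dendritic cell markers 0.00 (7 of 14 higher, 0.779). None of the bright markers passed singly, with Cd2 at 0.16 ± 0.18, Cd68 at -0.15 ± 0.12, Apoe at -0.20 ± 0.18, Ly86 at -0.26 ± 0.34, Itgb3 at 0.22 ± 0.11, Cr1l at -0.08 ± 0.25 and Pecam1 at -0.01 ± 0.11.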

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

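The tests on the chromosome of Rras2, on splits with the array sets held, on matched random lists and on the interferon list were chosen after the result was seen, and so was the block on the array sets. In the 4 WT arrays 156 genes and list means were checked for 1 array far from the other 3, 13 were found, and about 7.80 are expected by chance. WT replicate 3 was the far array in 8 of the 13. It was highest for the kinase gene Pdk1 (5.89), for Nupr1 (5.19), for Ccnd2 (6.48) and for the DNA repair genes Rnf8 (6.15) and Nhej1 (5.18), and lowest for Vsig10 (3.44), Gpr174 (5.24) and the monocyte, macrophage and dendritic cell list mean (4.84). WT replicate 1 was lowest for Rrp9 (5.90) and Pax5 (9.61) and highest for Tnfrsf17 (4.31). WT replicate 4 was lowest for Decr1 (5.29) and Oasl1 (5.52). For Pdk1 and Rnf8 the other 3 WT arrays held 1 value each, 5.79 and 5.99. The expected 7.80 takes values without such ties, whereas 1070 tested genes held 1 value on 3 or more WT arrays. An excess over chance is therefore not shown.

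Of the 20 genes of lowest p, 11 lie on the chromosome of Rras2 (Fisher's exact p = 1.12e-07) and 9 on others. That test asks only for the chromosome. In gene order the 11 sat 11 to 191 genes from Rras2, with a median of 81 against 337 for the chromosome's other tested genes. With the array sets as a block the excess stayed (Fisher's exact p = 1.38e-06), which argues against the sets as its source. Fisher's test takes clustered genes as independent, so these p-values are likely too small. Without Trim genes and predicted genes the excess was smaller, at 6 of the 20 (Fisher's exact p = 0.00451), between the bounds set for and against 1 gene cluster. These kinds were chosen after they were seen among the 11, so a smaller excess was likely to follow. That p therefore cannot decide between 1 co-regulated gene cluster and a wider region. Nucb2, Gprc5b, Gdpd3, Inppl1 and Alg8 sat 11, 23, 95, 129 and 191 genes from Rras2, outside the Trim genes at 80 to 83. A candidate explanation is a chromosome segment of another strain carried along with the targeted allele, which would alter levels or probe binding of neighbouring genes in both directions; neither the breeding of the mice nor strain variants in the probes were tested here. For the count of 2 genes past the threshold, 2 of the 35 splits of the arrays gave as many, the real one included, so chance is not excluded, but the other was the split along the array sets, which called 5014 genes and points to that structure of the samples. With the sets as a block the same 2 genes passed and 1 of the 34 splits that can be fitted, the real one, gave as many (highest other 1). Only 18 of these splits keep the number of arrays of each set in each group. The smallest p these allow is 0.0556, so this count cannot decide on chance.

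Lower MYC and energy lists appear with the array sets as a block, and leftover spread was weighed with 10000 random lists matched on how their genes move with it. The MYC list lay at the 0.010 percentile of these. The random lists drew genes singly, whereas the MYC genes move together (estimated correlation 0.29 with the block). Means of correlated genes vary more than such draws, so this percentile cannot decide on leftover spread. Oxidative phosphorylation (93.6), the tricarboxylic acid cycle (10.6), fatty acid oxidation (5.20), mitochondrial import (22.2) and mitochondrial DNA maintenance (87.7) lay within what the random lists give. Glycolysis (2.08) lay between the bounds. Without WT replicate 3, which sex-linked genes also set apart, 64.2% of the blocked MYC shift was left, between the bounds set for and against that array as its source. Of the 34 splits that can be fitted with the block, 3 gave the MYC list a shift as large for its error (real 2.57, highest other 4.32), so chance is not excluded. Among the 18 of them that keep the number of arrays of each set in each group only 1, the real one, was as large (next 2.26), which cannot decide it, since the smallest p these allow is 0.0556, so an effect of the genotype stays open.

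The higher interferon list may come from RRas2-deficient replicate 3 alone, since 2.31% of the shift was left without it. Interferon genes on the chromosome of Rras2 are argued against, since 104% was left without them. Of the 35 splits 13 gave a difference as large (real 0.26, highest other 0.38), so chance is not excluded. Monocyte, macrophage and dendritic cell markers were highest on that array too (list mean 5.28), and neither such cells left by the sort nor another source in that 1 sample was tested. For the count of 5 lists past the threshold 29 of the 35 splits gave as many (highest other 28), so chance is not excluded.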

How the results depend on the processing

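The array spread settings and the lists without genes of the chromosome of Rras2 were chosen after seeing the data, the others before. Over the alternatives 2845 of the values of named genes kept their direction and side of the threshold, 27 lost the call, 2 gained it and 55 moved. Of the list values 770 kept both, 55 lost the call, 183 gained it, 199 moved and 19 reversed. Rras2 stayed negative and short of the threshold throughout, from -0.59 to -1.50. The cause of the changes below was not tested, except where fewer arrays or probes enter. Genes past the threshold (2, both lower) were 1, lower, with centred arrays and with all probes. With array weights, which ran from 0.293 to 6.61, they were 5 (1 higher, 4 lower). They were 0 with the replicate number as a block (which also sets WT replicate 4 aside), with the plain t-test and on the 4 wider arrays. Calls on the 3 narrower arrays are not counted, since 1 of these is from deficient cells. Leaving out arrays gave 0 to 2 genes, all lower. Every gene called in any setting (Gm1966, Trim12a, Gm4759, Hbb-bh1, Trim12c, Trim30b) lies on the chromosome of Rras2. Gm4759 was called in 2 settings and Hbb-bh1, Trim12c and Trim30b in 1 each. Hbb-bh1 was called only with the block and without RRas2-deficient replicate 2. All settings refit the same 7 arrays or some of them, so these calls are not independent. Lists past the threshold (5) were 2 with quantile normalization and with centring, 8 with array weights, 3 with the replicate block, 18 with the array set as a block, 20 on the wider arrays, and 1 to 21 on leaving out arrays. They were 0 with estimated correlation, fry or exact permutation. Whether replicate numbers pair the samples cannot be told, because deviations followed the array sets. Same-numbered deviations correlated at -0.59, 0.78 and 0.66. Differently numbered ones correlated at 0.72 and 0.66 within a set and at -0.81 to -0.59 between sets. Reversed list means were -0.24 for the dark zone on the wider arrays, and 0.23 for immediate early genes and -0.034 for interferon on the narrower ones, where 1 deficient array is assumed to vary like the WT arrays. With and without the block, leaving out 1 array moved S phase between -0.23 and 0.24, MYC -0.31 and 0.027, ATF4 -0.26 and 0.012, class switching -0.18 and 0.17, dark zone -0.24 and 0.27, immediate early -0.58 and 0.21, mitochondrial DNA maintenance -0.14 and 0.16, mitosis -0.35 and 0.23, and oxidative phosphorylation -0.22 and 0.29. Dim genes near 3.48 have little signal over background, which limits their differences.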

Other observations

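Small RNAs of the nucleolus and the Cajal body, which guide chemical modification of other RNAs, followed the array sets, a comparison chosen after the result was seen. Of 65 such genes tested, 44 were lower on the 4 wider arrays past an adjusted p of 0.05, 0 were higher, and the median difference was -1.68. Between genotypes their median was -0.46, and -0.15 with the array set as a block. Over all genes 5572 passed between the 2 sets, 3989 higher and 1583 lower on the wider arrays. The sets were parted by the interquartile range of these same values, so many calls between them were to be looked for. These counts describe how the sets differ and do not test that they do.

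The X-inactivation transcript Xist read 6.61 in WT replicate 3 and 9.43 to 10.3 on the other 6 arrays. The Y-linked genes Eif2s3y, Kdm5d and Uty read 6.75, 6.48 and 5.93 in WT replicate 3. On the other arrays they read 3.09 to 4.40, 3.68 to 4.97 and 3.08 to 4.31. WT replicate 3 thus stood apart from the other 6 arrays in sex-linked genes, as a male or mixed sample would, and the labels give no sex.

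The embryonic globin gene Hbb-bh1, on the chromosome of Rras2, read 6.36 and 6.23 in WT replicates 3 and 4 and 2.88 to 3.30 on the other 5 arrays, including WT replicates 1 and 2 (3.08 and 3.27). It was singled out after its values were seen.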
